A study of Mus musculus with 6 samples.

How the data were processed

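RNA of cultured mouse spermatogonial stem cells was measured on 6 single-colour Agilent microarrays, 3 of cells given 0.01 M captopril for 24 h and 3 of cells given sterile water. Per the labels' protocols, RNA was isolated with Trizol and a mirVana kit, amplified, labelled with Cy3 and hybridised, and the samples were independent experiments. Whether these were separate animals is not given in the sources used here. All arrays lie on 1 slide and were scanned on 1 date per the file headers, with water replicates 2 and 3 in slide row 1 and the other 4 arrays in slide row 2.

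The spot intensity values were made by Agilent Feature Extraction, version 11.5.1.1 per the file headers and version 10.7 per the submitters' processing notes. Per the file headers, this program subtracted the background within each array and gave each spot flags for signal well above background, saturation and outliers. The log2 values of the deposited series table were made by the authors from these signals by steps not given in the sources used here. Set against log2 of the processed signal, each of its columns had r = 1, with 100% of the values within 0.01 of a constant difference. Its column medians were −3.81, −4.25 and −3.79 for water replicates 2, 3 and 4, and −3.73, −3.64 and −3.63 for captopril replicates 2, 3 and 4, with the 75th percentile close to 0. Its scale is therefore log2 and its centring is close to the 75th percentile of each array, and it was used only as an alternative.

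Log2 of the processed signal was taken and the 75th percentile of each array, over spots that were neither controls nor outliers by the program's flags, was subtracted. That percentile was 2800 to 3424 on water replicates 2 and 4 and captopril replicate 2, 2780 on captopril replicate 3, 1885 on captopril replicate 4 and 1875 on water replicate 3. Spots of the same probe were averaged, which concerned 432 of 55681 probes, and 63 probes lacked at least 1 array through an outlier flag. Probes were named through their transcript accession in the RefSeq gene table of assembly GRCm38.p6. This gave 26762 probes 1 symbol and left 28919 unnamed, and 98.1% of the accessions of curated messenger RNAs matched. No coordinates are given, since the array design used another assembly. Each gene was represented by its brightest probe over the 6 arrays among those well above background on at least 3 arrays. A gene not well above background on any array of a group is given as a bound.

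Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. The 30 gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the 30 lists. All of these p are two-sided. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The groups, tests, gene lists and alternatives were chosen before the data were examined. The genes named are of 3 kinds. The first are the 10 largest rises and the 10 largest falls among genes past the threshold whose captopril arrays all lie beyond all water arrays, with systematic symbols left out. The second are 22 genes of the renin-angiotensin system, stem cell state and MAPK signalling, some of which are not reported here. The third are, per list, up to 4 members past the threshold over all genes with the smallest p, or the member with the smallest p where none passed. The same rule was applied, after the data had been seen, to the fit without water replicate 3.

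The code was tested on simulated data with the spread of these arrays and 200 changed genes among 14860, of which 100 changed 2-fold and 100 changed 4-fold. The comparison of 6 arrays called 6 unchanged genes and that of 5 arrays called 7. Of 50 lists of unchanged genes, 1 had a camera p under 0.05 in each comparison. The noise was drawn for each gene independently, so these lists do not show how camera behaves where genes vary together. It was also drawn alike on all arrays, so the shares of changed genes recovered need not hold where arrays differ in spread.

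The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling by the median of each array, no filter on dim probes, a filter on all 6 arrays, the mean of a gene's probes, the authors' table, a variance trend with robust eBayes, the replicate number as a block, the slide row as a block, slide row 2 alone, other thresholds, and each array left out in turn. The files used here have no column of mean spot signal, so normexp was run on the median spot signal and the median local background. Control spots were left out of every test.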

Results

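Cultured mouse spermatogonial stem cells, the germline stem cells of the testis, were grown with mouse embryonic fibroblasts as feeder cells. They received 0.01 M captopril, a drug that inhibits angiotensin-converting enzyme (ACE), or sterile water as the control, and RNA was taken after 24 h. The labels give 0.01 M for the water as well, so what this number refers to is not settled. Transcripts were measured on single-colour Agilent arrays, with 3 captopril and 3 water arrays that the labels describe as independent experiments. The arrays carry the replicate numbers 2, 3 and 4 in both groups. Between 52.1% and 60.5% of the spots on an array were well above background, and 14860 named genes entered the tests. The number of arrays limits the precision. The title of the series links somatic ACE to self-renewal and to mitogen-activated protein kinase (MAPK) signalling. The comparison therefore asks which genes, stem cell markers and MAPK genes differ with captopril. The arrays do not measure ACE activity.

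Genes of G2 and mitosis were lower after captopril than in water. The median log2 fold change (captopril minus water) of the 29 measured members of the G2/M and mitosis genes list was −0.57, and 25 of the 29 had a negative value (camera, adjusted p = 2.0e-06 over 30 lists). With an estimated correlation between genes the adjusted p = 0.109, and the rotation test fry gave an adjusted p = 0.00030. The median level of the list, relative to each gene's own median over the 6 arrays, was 0.35, 0.35 and 0.31 on water arrays 2, 3 and 4. It was −0.19, −0.20 and −0.16 on captopril arrays 2, 3 and 4. Water replicate 3 stood high for most lists, at 0.55 for stem cell markers, 0.50 for ribosomal protein genes and 0.80 for fibroblast markers, and its 0.35 here lies below those levels. The groups did not overlap (exact permutation test, two-sided p = 0.1, the smallest that 3 arrays against 3 can give). The level of water replicate 3 carries its shift across most lists, so this separation rests mainly on water replicates 2 and 4. Within slide row 2, which held all captopril arrays but of the water arrays replicate 4 alone, the median was −0.49, a value that carries no spread between water arrays. Adjusted over the list alone, 3 members passed 0.05, all of them lower, and over all genes tested none did. These were the cyclin Ccna2 (log2 fold change −0.95, SE 0.22), the kinetochore protein Cenpf (−1.06, SE 0.22) and the spindle protein Nusap1 (−1.34, SE 0.34), of which Ccna2 and Nusap1 are named because of their values.

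**Figure D1:**
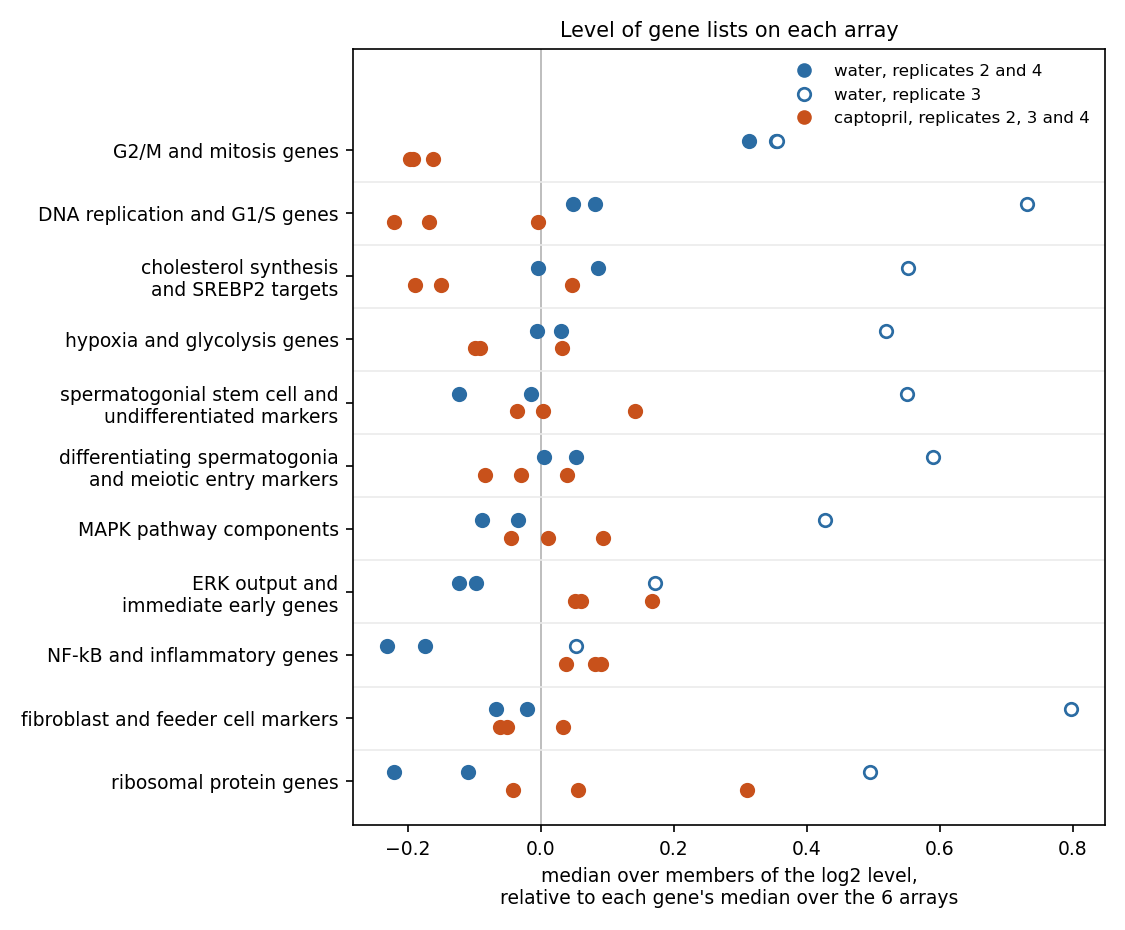
Level of 11 gene lists on each of the 6 arrays: the horizontal axis gives the median over the members of a list of the log2 level relative to each gene's median over the arrays, and each point is 1 array. For genes of G2 and mitosis the water arrays lie at 0.31 to 0.35 and the captopril arrays at −0.20 to −0.16, while water replicate 3 lies apart from the other water arrays for most of the other lists shown.

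Genes of DNA replication and the G1/S step were lower as well, by a smaller amount once a single water array was left out. Over all arrays the median log2 fold change of the 30 measured members was −0.41, with 27 negative values (camera, adjusted p = 0.00027). With an estimated correlation the adjusted p = 0.716. On captopril replicates 2, 3 and 4 the list stood at −0.22, −0.17 and −0.004, the last of these close to water replicate 4. On water replicate 3 it stood at 0.73, against 0.08 and 0.05 on water replicates 2 and 4. Without that array the median was −0.20, with 29 of 30 negative values (camera, adjusted p = 1.5e-05; adjusted p = 0.667 with an estimated correlation). Within slide row 2, with a single water array, it was −0.18. No member passed the test alone, in either fit and over the list or over all genes. The member with the smallest p was Rrm2, a subunit of ribonucleotide reductase, at −0.86 (SE 0.23, adjusted p = 0.518 by limma).

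No single gene passed the test when all 6 arrays were compared. limma called 0 of 14860 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.455. At an unadjusted p under 0.05 there were 1224 genes, 492 higher and 732 lower with captopril, where 743 would be found by chance. In 3192 genes (21.5%) the captopril and water arrays did not overlap, against 10% by chance. In simulated data with each gene's spread within groups, this comparison recovered 5% of genes changed 2-fold and 61% of genes changed 4-fold. The simulated noise was alike on all 6 arrays, whereas the real spread was larger among the water arrays, so these shares need not hold here.

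Water replicate 3 stood apart from every other array, including those of its own group. Its correlation with the other arrays was 0.878 to 0.893 over 32380 probes, while the other 5 arrays correlated at 0.970 to 0.991 with each other. The median SD per gene was 0.449 (log2) over the 3 water arrays and 0.204 over the 3 captopril arrays. Over water replicates 2 and 4 alone it was 0.108. Each count was therefore also taken without this array, a choice made after the data had been seen, which leaves 2 water against 3 captopril arrays.

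**Figure D2:**
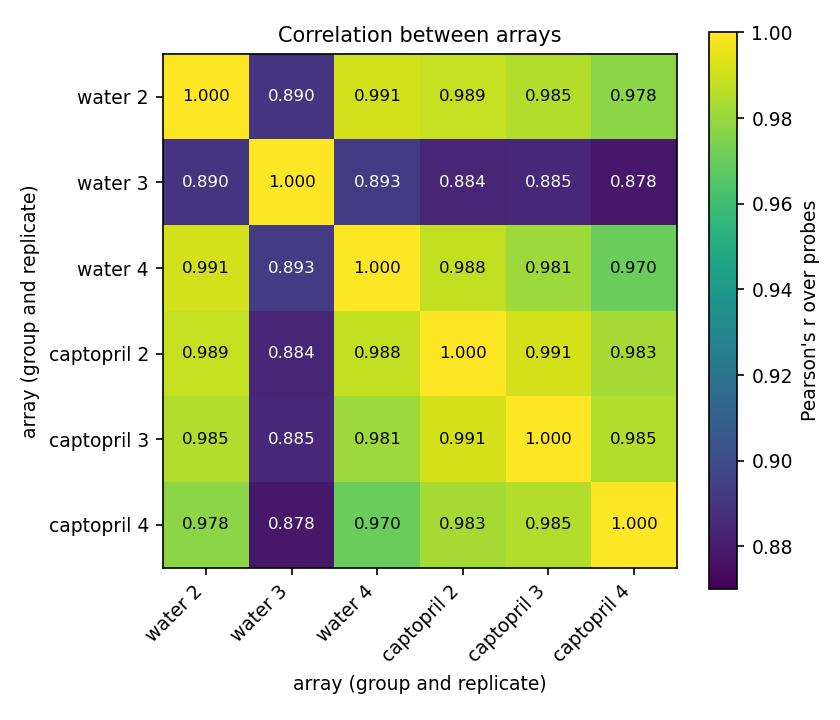
Pearson's r between each pair of the 6 arrays over 32380 probes, with the arrays named by group and replicate on both axes and the value printed in each cell. Water replicate 3 has r of 0.878 to 0.893 with the others, and all other pairs have r of 0.970 to 0.991.

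Without water replicate 3, captopril raised transcripts that included Ptpn22, Csf2 and Icos, and lowered others that included the angiotensin receptor gene Agtr2 and the spindle motor gene Kif11. limma then called 92 genes at an adjusted p under 0.05, of which 62 were higher and 30 lower, and 88 of them changed at least 2-fold (61 higher, 27 lower). All 92 had the same sign over the 6 arrays, which adds little, since 5 of these arrays called the genes. In 80 of the 92 all captopril arrays lay beyond all 3 water arrays. In 12 of the 92, a group was not well above background on any of its arrays. At an unadjusted p under 0.05 there were 2839 genes, 1799 higher and 1040 lower, the opposite balance to that over 6 arrays. In 6373 genes (42.9%) the groups did not overlap, against 20% by chance. limma called 39 genes (19 higher, 20 lower) with each array's median for scaling, 0 with quantile normalization (3007 at an unadjusted p under 0.05) and 0 without a filter on dim probes (2846). It also called 0 when water replicate 2 (1766 at an unadjusted p under 0.05), water replicate 4 (1255), captopril replicate 3 (1972) or captopril replicate 4 (3436) was left out as well. In simulated data the comparison of 5 arrays recovered 36% of genes changed 2-fold and 85% of genes changed 4-fold.

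Among called genes whose groups did not overlap, with systematic symbols left out, the largest rise was that of Ptpn22 (NM_008979). It encodes a phosphatase that restrains lymphocyte receptor signalling. Its log2 level rose from −4.58 ± 0.11 (SD, n = 2) in water to −2.10 ± 0.28 (n = 3) with captopril, a log2 fold change of 2.48 (SE 0.20, limma adjusted p = 0.036). It stood at −3.49 on water replicate 3, below all captopril arrays. Csf2 (NM_009969), which encodes the cytokine GM-CSF, rose by 1.86 (SE 0.14, adjusted p = 0.036), and was well above background on 2 of the 3 water arrays, without replicate 4. The T cell costimulator Icos rose by 1.79 (SE 0.17), and its other probe showed 1.57. Slc38a5, an amino acid transporter, rose by 1.84 (SE 0.22). Rnase6, Pdzk1ip1, Pla2g12b and Prss12 rose by 1.67, 1.62, 1.62 and 1.61. Fbxw13 rose as well (adjusted p = 0.048), but it was well above background on 1 of the 3 water arrays, replicate 2, so that its fitted value of 2.27 rests partly on signals at background. Tmem204 was not well above background in water and was at least 2.16-fold higher with captopril, where its adjusted p was 0.041.

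Among the falls, Agtr2 (NM_007429), the type 2 angiotensin II receptor, was not well above background on any captopril array and was at least 3.37-fold lower there (adjusted p = 0.036). Its log2 level was −3.71, −2.15 and −3.06 on water replicates 2, 3 and 4. Heyl, a Notch target, was likewise at least 2.30-fold lower, Brinp3 at least 1.72-fold and Klf14 at least 1.20-fold. These bounds set the water mean against the lowest signal that was well above background on each captopril array. Kif11 (NM_010615), the motor that separates the spindle poles, fell from 0.51 ± 0.17 (SD, n = 2) to −1.32 ± 0.28 (n = 3), a log2 fold change of −1.83 (SE 0.20, adjusted p = 0.036). On water replicate 3 it stood at −0.79. Nrep fell by 1.95, Stfa3 by 1.89, Cd3g by 1.57, Cbfa2t3 by 1.52 and the cardiac troponin T gene Tnnt2 by 1.41. Cd3g was well above background on 2 of the 3 captopril arrays. Most of these genes are dim: the median log2 level of the 92 called genes was −2.92, against 0.32 for all genes tested.

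**Figure D3:**
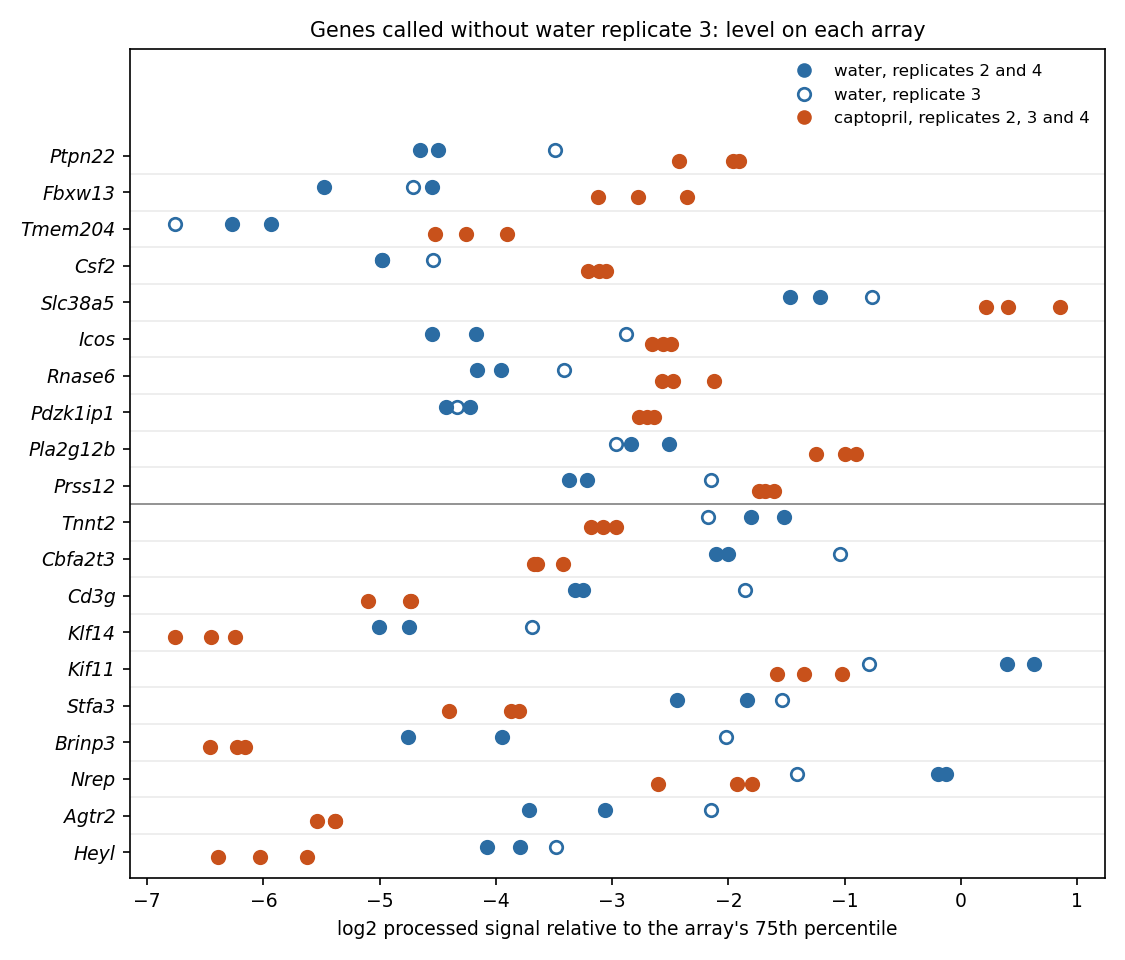
Log2 processed signal, relative to the 75th percentile of its array, of the 10 genes that rose most and the 10 that fell most. They are ranked among genes called without water replicate 3 whose groups did not overlap, with systematic symbols left out. Each point is 1 array, and the open circle is water replicate 3, which did not enter the test. In each gene all 3 captopril arrays lie beyond all 3 water arrays. The lowest signal well above background was −5.54 to −4.86 across arrays, and points below that of their array are not measured levels. Some points above it, such as Csf2 on water replicate 4, were not well above background either.

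In the same fit of 5 arrays, all 29 genes of G2 and mitosis had negative values, with a median of −0.51 (camera, adjusted p = 2.2e-13). The adjusted p was 0.0925 with an estimated correlation and 0.0012 by fry. Adjusted over the list alone 14 members were lower, and over all genes Kif11 alone. Cenpf stood at −0.96 (SE 0.16, adjusted p = 0.056).

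Spermatogonial stem cell and undifferentiated markers did not move as a group. The median of the 30 measured members was −0.08 over 6 arrays (camera, adjusted p = 0.774), with 12 positive and 18 negative values, and 0.13 without water replicate 3 (adjusted p = 0.822). No member passed over all genes, and over the list alone only T, the brachyury gene, did in the fit of 5 arrays (1.32, SE 0.21). Gfra1, the GDNF co-receptor, had a log2 fold change of 0.60 with an SE of 1.02, since its level was −4.88 on water replicate 3, where it was not well above background, and −1.17 and −1.20 on water replicates 2 and 4. Without that array its value was −0.64 (SE 0.47). Its partner Ret stood at −0.39 (SE 0.30), and the transcription factors Zbtb16, Etv5, Bcl6b and Id4 stood at −0.01, 0.11, 0.36 and −0.14, with SE of 0.25 to 0.35. In the fit of 5 arrays Ret stood at −0.10, and Zbtb16, Etv5, Bcl6b and Id4 at 0.16, 0.37, 0.64 and 0.23, with adjusted p of 0.142 to 0.741 for these 5 genes. Nanos2, Pou5f1 and the germ cell gene Ddx4 stood at −0.51, 0.60 and −0.71, and their adjusted p were 0.624, 0.658 and 0.631. Leaving out water replicate 3 put them at −0.33, 0.04 and −0.25, with adjusted p of 0.370, 0.911 and 0.388. Markers of differentiating spermatogonia and meiotic entry had a median of −0.19 (camera, adjusted p = 0.205), and of −0.12 without water replicate 3 (adjusted p = 0.082). Kit stood at −0.60 and Stra8 at −0.41, and without that array at −0.23 and −0.28, neither past the test in either fit. Meioc had the smallest p of that list (−1.20, SE 0.27, adjusted p = 0.455), and without water replicate 3 it was the single member lower adjusted over the list alone, with none over all genes. In that fit its chosen probe gave −1.03 and its other probe −0.47.

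MAPK pathway components showed no shift as a group either. The median of their 83 measured members was 0.02, with 45 positive and 38 negative values (camera, adjusted p = 0.911), and 0.12 without water replicate 3 (adjusted p = 0.822). The member with the smallest p over 6 arrays was Dusp2, a MAPK phosphatase, at −1.80 (SE 0.38, adjusted p = 0.455), and at −1.60 without that array (SE 0.36, adjusted p = 0.090). The kinase genes Mapk3, Mapk8 and Mapk14 had log2 fold changes of 0.65, −0.47 and −0.28, with SE of 0.27 to 0.40. Over the 5 arrays without that water array Mapk3 stood at 0.19 and Mapk8 at −0.25. Their probes did not always match: in that fit the chosen probe of Mapk14 gave 0.12 and its other probe −0.95. These values concern transcripts and say nothing of kinase activity. Genes induced by ERK, the MAPK that growth factors activate, had a median of 0.14 (camera, adjusted p = 0.188) and of 0.30 without water replicate 3 (adjusted p = 0.187; fry, adjusted p = 0.036; adjusted p = 0.667 with an estimated correlation). In that fit 6 of their 26 measured members were higher and 1 was lower, adjusted over the list alone, and none over all genes. Egr1, an immediate early gene, stood at 0.80 (SE 0.23, adjusted p = 0.518) over 6 arrays and at 0.87 (SE 0.18, adjusted p = 0.079) without that array. Dusp6, a phosphatase that ERK induces, stood at 0.13 (SE 0.27), Ccnd1 at 0.07 (SE 0.35) and Ccnd2 at 0.39 (SE 0.39). In the fit of 5 arrays they stood at 0.36, −0.27 and −0.03, none past the test. Genes that respond to GDNF, the growth factor of these cells, had a median of 0.08 (camera, adjusted p = 0.892), and of 0.18 without water replicate 3 (adjusted p = 0.735). In that fit 2 members were higher and 1 lower adjusted over the list alone, and none over all genes.

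The gene of the drug's target, Ace, was measured above background on all 6 arrays and stood at 0.15 (SE 0.24, adjusted p = 0.846). The 12 measured genes of the renin-angiotensin and kinin system had a median of −0.28 (camera, adjusted p = 0.283). The list stood at 0.79 on water replicate 3 and between −0.06 and 0.03 on the other arrays, and without that array its median was −0.06 (adjusted p = 0.687). Of these, Agtr2 alone passed over all genes without water replicate 3, and Agtr1a stood at −0.37 (SE 0.30) over 6 arrays and at −0.11 (SE 0.20) without that array. Adjusted over the list alone, 1 member was lower and 1 higher in that fit. The higher one was Kng1 (0.71, limma adjusted p = 0.096 over all genes). Over the 6 arrays Agtr2 was at least 4.48-fold lower (adjusted p = 0.455).

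Of the other lists, 1 passed with camera over 6 arrays, namely genes of hypoxia and glycolysis. Their median was −0.19, with 26 of 33 negative values (adjusted p = 0.024; adjusted p = 0.716 with an estimated correlation). With the slide row as a block, which sets water replicate 4 alone against captopril, the median was −0.01 (adjusted p = 0.054). Without water replicate 3 it was −0.08, with 19 negative values (adjusted p = 0.032; adjusted p = 0.667 with an estimated correlation). In that fit 3 members were lower adjusted over the list alone and none over all genes. The level of the list overlapped between these groups, at 0.030 and −0.006 on water replicates 2 and 4. On captopril replicates 2, 3 and 4 it was −0.09, −0.10 and 0.032. The hypoxia target Ndrg1 had the smallest p of that list (−1.55, SE 0.33, adjusted p = 0.455). Cholesterol synthesis genes had a median of −0.32 (camera, adjusted p = 0.079). Without water replicate 3 it was −0.21, with 21 of 24 negative (camera, adjusted p = 0.0013, and adjusted p = 0.667 with an estimated correlation). The level of this list overlapped as well, at 0.09 and −0.004 on water replicates 2 and 4. On captopril replicates 2, 3 and 4 it was −0.19, −0.15 and 0.05. Ribosomal protein genes had a median of 0.05 (camera, adjusted p = 0.597). Without water replicate 3 it was 0.28, with 41 of 44 positive (camera, adjusted p = 0.0049, and adjusted p = 0.825 with an estimated correlation). This list stood at 0.31 on captopril replicate 4, against −0.04 and 0.06 on captopril replicates 2 and 3. On water replicates 2 and 4 it stood at −0.11 and −0.22. With quantile normalization of these 5 arrays the ribosomal median was 0.07 (adjusted p = 0.555).

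Markers of the fibroblast feeder cells had a median of −0.25 over 6 arrays (camera, adjusted p = 0.079). On water replicate 3 this list stood at 0.80, and on all other arrays between −0.07 and 0.03, and without that array the median was 0.05 (adjusted p = 0.535), while the mean was −0.07 and the direction of the test was down. That median was −0.03 with quantile normalization and −0.08 with scaling by the array median. Adjusted over the list alone, 1 member was then higher and 4 were lower, and over all genes 1 was lower. This was the collagen Col5a2, which fell (−1.40, SE 0.21, adjusted p = 0.049). Markers of Sertoli cells, Leydig and peritubular cells, macrophages and leukocytes, and spermatocytes and spermatids had medians of −0.10, 0.20, 0.04 and 0.03 over 6 arrays, with adjusted p of 0.597, 0.359, 0.695 and 0.999. Over the 5 arrays these medians were 0.08, 0.17, −0.09 and 0.18, with adjusted p of 0.991, 0.687, 0.467 and 0.599; for Sertoli cells the direction of the test was down. For spermatocytes and spermatids over 6 arrays the mean was −0.03 and the direction of the test was down. Among the Sertoli markers Gdnf, the growth factor that these stem cells depend on, rose without water replicate 3 (1.07, SE 0.15, adjusted p = 0.043). Adjusted over the list alone, 3 Sertoli markers were higher and 2 lower in that fit.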

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

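The fits without water replicate 3 were chosen after the results over 6 arrays were seen. Over 6 arrays limma called 0 genes under each alternative that kept all arrays and at adjusted p under 0.1 and 0.01. Leaving out 1 array gave 0 to 92 genes, and 0 to 88 changed at least 2-fold, with 92 and 88 only without water replicate 3. Scaling by the median moved the median log2 fold change of all genes to −0.33, and within slide row 2 it was 0.11.

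Without water replicate 3, limma called 0 genes with quantile normalization (0 at least 2-fold), where the smallest adjusted p was 0.0567. It called 39 with median scaling (39 at least 2-fold, all 39 among the 92) and 0 without a filter on dim probes (0 at least 2-fold), which tests 20268 genes. At adjusted p under 0.1 it called 627 and under 0.01 it called 0. Leaving out another array gave 0 to 87 genes (0 to 87 at least 2-fold), where the 87, without captopril replicate 2, were 40 higher and 47 lower with 46 among the 92, and a lone water array is then assumed to vary like the others. The other alternatives gave 74 to 137 genes, of which 62 of 91 (normexp), 59 of 74 (variance trend), 64 of 113 (filter on all 6 arrays), 88 of 137 (mean of probes) and 79 of 79 (the authors' table) were among the 92. All 92 kept their sign wherever tested, though these fits reuse arrays that called them. Except where a construction is named, the cause was not tested.

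With the replicate number as a block (replicate block), 0 genes were called over 6 arrays and 215 without water replicate 3 (215 at least 2-fold, 96 higher and 119 lower, 63 of them among the 92). The deviations of arrays of the same number had r of −0.02, 0.02 and −0.19 for replicates 2, 3 and 4. Of 6 arrays, 1 correlated best with its own number. These deviations were taken from group means that include water replicate 3, which weighs on those of water replicates 2 and 4. The check therefore cannot decide whether arrays of the same number are paired. The block fit without water replicate 3 also leaves little to estimate the spread from, which limits its 215 calls.

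The G2/M and mitosis genes list was lower in 19 of 19 alternatives, with medians of −0.88 to −0.49 and adjusted p of 2.2e-13 to 0.109, and passed in 18. The exception was the estimated correlation, with a median of −0.57 (adjusted p = 0.109), and −0.51 without water replicate 3 (adjusted p = 0.0925). The slide row as a block and slide row 2 alone both set water replicate 4 alone against captopril, with a median of −0.49, and add no independent evidence. The DNA replication list passed in 17 of 19. The exceptions were the estimated correlation (−0.41, adjusted p = 0.716) and fry (−0.41, adjusted p = 0.308), and without water replicate 3 likewise (−0.20, adjusted p = 0.667, and −0.20, adjusted p = 0.166). Among results that passed no test, the sign changed in 46 pairs of list and alternative and 30 of named gene and alternative over 6 arrays, and in 28 and 22 without water replicate 3. Of the 92 genes, 75 lie among the dimmest genes when all genes tested are split by level into 3 equal parts.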

Other observations

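All tests on water replicate 3, the test of the germ cell share and both tests on dim genes were chosen only after related results had been seen. The test on other probes of the G2 and mitosis genes and the counts of splits were set before their own results were seen, but the former and the splits of 5 arrays use the fit without water replicate 3, which was itself chosen after the data had been seen.

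Without water replicate 3, genes of NF-kB signalling and inflammation had a median of 0.37 over 25 members (camera, adjusted p = 0.119; fry, adjusted p = 0.036; adjusted p = 0.667 with an estimated correlation). Over 6 arrays the median was 0.34 (fry, adjusted p = 0.252), with 1 member higher and 1 lower adjusted over the list alone. Without water replicate 3, 10 members were higher and 2 lower over the list alone, and over all genes Csf2 alone was higher. Among those lower was Il6, an inflammatory cytokine named here after its values were seen, which was not well above background on any captopril array and at least 1.25-fold lower there (adjusted p = 0.076). Lysosome and autophagy genes had a median of 0.24 without that array (camera, adjusted p = 0.246, fry, adjusted p = 0.030, and adjusted p = 0.667 with an estimated correlation). In that fit the protease gene Ctsk stood at 0.92 (SE 0.15, adjusted p = 0.054). Over 6 arrays the median of this list was 0.11 (fry, adjusted p = 0.308). TGF-beta and BMP response genes had a median of 0.16 without water replicate 3 (camera, adjusted p = 0.535, fry, adjusted p = 0.036, and adjusted p = 0.750 with an estimated correlation). In that fit 3 members were higher adjusted over the list alone and none over all genes. Over 6 arrays their median was −0.10 and the direction of camera was down (fry, adjusted p = 0.948). Of the NRF2 and glutathione genes, the quinone reductase gene Nqo1 rose by 1.29 without water replicate 3 (SE 0.18, limma adjusted p = 0.043). Of the replication-dependent histone genes, H2ac4 fell by 1.06 in the same fit (SE 0.15, adjusted p = 0.043), though near-identical copies make the identity of a histone probe uncertain.

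Of the probes without a gene symbol, 13081 were tested. limma called 0 of them over 6 arrays (1380 at an unadjusted p under 0.05) and 76 without water replicate 3, of which 58 were higher and 18 lower.

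Water replicate 3 stood apart from the other arrays, and its deviation was taken from the mean of water replicates 2 and 4. Over 2915 genes with a pair of probes, the deviations of probes of the same gene correlated at r = 0.0591 (across genes, 95% interval 0.0215 to 0.104). The same r was 0.44 for the effect of captopril, and 0.0868 for the small difference of water replicate 4 from water replicate 2. The low r of so large a deviation argues against whole transcripts at other levels as the main source. Blocks of the array grid held 1.98% of the variance, which argues against a local fault. The added E1A control probes, of which 8 had signal, spread 0.121 times as much as genes of like signal. Each control value is a median over its spots, while the genes are single spots, and this alone lowers the ratio. The ratio therefore cannot decide on a fault of hybridisation or scanning common to all spots. In 35% of the genes a probe was lower and the other higher, more than 2-fold apart, against 2.74% between water replicates 4 and 2. A candidate explanation is a change specific to each probe, as loss of part of each transcript would give, but probe positions were not used here and other causes at the level of probes stay open.

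The lower level of G2 and mitosis genes was also seen on probes that the test did not use. In the fit without water replicate 3, the 8 other probes of 6 of these genes were reduced to a median per gene. These 6 values had a median of −0.776 (95% interval over genes −0.996 to −0.445), which argues against a fault of single probes. The interval carries no spread between arrays. In the same fit the median of the stem cell list was 0.128, with 17 positive and 13 negative members. That of the fibroblast list was 0.05. The SE of the mean of the stem cell list, 0.0839, is taken over members and carries no spread between arrays. These medians show no lower share of germ cells among feeder cells, but they cannot exclude one, and the germ cell gene Ddx4 stood at −0.25. With 10 splits of the 6 arrays a share under 0.05 cannot be reached. In 1 split, the real one, the camera p was as small (6.6e-08). Splits that exchanged water replicate 3 with a captopril array gave a camera p of 2.0e-05, 2.8e-05 and 3.7e-05. The remaining splits gave a camera p of 0.11 to 0.75, so the result rests mainly on water replicates 2 and 4. A direct effect of captopril on cell division was not tested and stays open.

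The genes called without water replicate 3 lie mostly among dim genes. Of the 92, 79.3% were well above background on all 5 arrays, against 95.2% of the genes tested, so the called genes passed less often. Genes were tested only if well above background on at least 3 arrays, so a low share was hard to reach. The share therefore does not exclude signals near background as a source of these calls. Under quantile normalization their median absolute log2 fold change was 0.98 times its value, at 1.26 against 1.28, while their adjusted p rose to at most 0.0817, which argues against differences in the distribution of signal as the source of their size. In 1 of 10 splits of the 5 arrays, the real one, there were as many genes (92, against 0 in the others), and 10 splits are too few for a share under 0.05.

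The other results were set against the same 10 splits of 6 arrays, which are too few for a share under 0.05. For the count of genes over 6 arrays, 10 of 10 splits gave as many (0, highest other 0), and for genes changed at least 2-fold likewise 10 of 10 (0, highest other 0). For the MAPK list 6 of 10 splits gave a camera p as small (real 0.850, smallest other 0.682), for the stem cell list 10 of 10 (0.619 and 0.0769), and for the DNA replication list 1 of 10 (1.8e-05 and 3.5e-04).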
